A study of Schizosaccharomyces pombe with 29 samples.

How the data were processed

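Polyadenylated RNA of 31 fission yeast libraries in 10 groups was analysed from 29 sample records. The 3 control count columns numbered 4, 5 and 6 were taken as replicates of the control set 2 record. This was done by elimination, since no other title holds these numbers. The labels' protocols name growth at 30 °C in YES medium, in log phase or for the earlier WT18 pair to a set density. The new libraries were made from RNA purified with hot acid phenol, with a stranded TruSeq mRNA kit, and sequenced on a NovaSeq instrument. The T4A libraries and 2 of the 4 WT18 libraries are re-analysed from earlier series per the labels. T4A has the same kit and a HiSeq instrument. The earlier WT18 pair has column-purified RNA, a stranded TruSeq total RNA kit after polyA selection and an older HiSeq instrument. Its strain is also of opposite mating type with other auxotrophic markers, so protocol, mating type and markers are confounded with that pair, and the sequencing source with T4A.

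The deposited table holds whole read counts per gene, which the authors made by aligning reads with HISAT2 2.1.0 to assembly ASM294v2, processing them with SAMtools and counting with HTSeq 0.10.0, per the submitters' processing notes. The strand setting of the counting is not stated, so counts of an antisense RNA may hold reads of the gene opposite. The authors' deposited tables, 1 per allele, give log2 fold changes of mutant over control by DESeq2, adjusted p-values by the same tool, and group means of the signal, which are counts divided by size factors. The mutant means of all 8 tables and the control means of the 3 set-1 tables were rebuilt from the deposited count columns to within 1%. The control means of the 5 set-2 tables were not: weighted sums of the 3 columns missed them by a median of 25% over genes. Their log2 fold changes are therefore quoted only as a further reference, and in these 5 alleles a gene holds with all 3 references when it was called in 1 direction against each control set and in the authors' deposited table.

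The count table has 6987 lines for 6986 gene IDs, of which 269 have no count in any library; 1 ID is listed again with no counts. Gene names, classes, exon lengths and order came from a reference annotation of assembly ASM294v3, which matched 6833 IDs; no coordinates are given, since the assembly differs from the authors'. Total counts ran from 15.2 M to 35.8 M per library.

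Each comparison was fitted on its own libraries with edgeR 4.0.16 (quasi-likelihood F test, TMM scaling, filterByExpr filter) under R 4.3.3, and p-values were adjusted over the genes tested by the Benjamini-Hochberg method. For a direct contrast these were the libraries of the 2 alleles and of the control set they share. A gene is called at an adjusted p under 0.05 and at least a 2-fold change, while rose and fell need the adjusted p only. Levels are CPM, counts scaled to the effective library total within each comparison. There were 8 comparisons of an allele with the control set the labels name, 5 direct contrasts of alleles and 1 of the control sets. Gene lists written from general knowledge were tested against all other genes with camera in limma 3.58.1 on voom values with a preset correlation of 0.01. Of 28 lists 24 could be tested; those past the threshold are given in the results. Across the 14 comparisons no list passed with a correlation estimated from the data. That estimate rests on the few libraries of each comparison, so a list that did not pass with it is not shown to be unchanged. Differences between the effects of 2 alleles were tested as contrasts within 1 edgeR fit. Overlaps were set beside the product of the list sizes over the genes tested, and correlations of effects beside 10 simulations of unchanged groups sharing a control.

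The comparisons, thresholds, gene lists and the rule for named genes were set before the data were examined. The rule names, per allele, the 8 coding genes with the largest rise and the 8 with the largest fall among called genes with an average log2 CPM of at least 2 whose mutant libraries all lie on 1 side of the controls, then 2 non-coding RNAs each way, and list members; direct contrasts name 3 each way. Named list members, and the choice among the genes of the rule, were picked after their values were seen.

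Alternatives were size factors of DESeq2 1.42.0, its Wald test, no filter beyond 1 count, no minimum fold, all groups of a control set in 1 fit, the control sets together, each library left out in turn, replicate number as a block, and for WT18 the new or the earlier libraries alone. The other control set alone was added after the authors' control means could not be rebuilt. Replicate numbers tracked the counts (every correlation of same-numbered residuals over 0.1) only for S2A-S7A against S2A (0.46, 0.11 and 0.20) and ALT-P6A against ALT-S5A (0.15, 0.23 and 0.24). No paired analysis was possible because the numbers do not match for T4A, the ALT alleles and WT18 against control set 2, and for the control sets. In counts simulated from the Y1F comparison, edgeR recovered 100% of genes changed by 2 on the log2 scale with 0 false calls (DESeq2 also 0); for WT18 it recovered 86% with 7 false calls.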

Results

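Polyadenylated RNA was sequenced from strains of fission yeast, Schizosaccharomyces pombe, that differ in the carboxy-terminal domain (CTD) of Rpb1, the largest subunit of RNA polymerase II. The CTD is a tail of repeated YSPTSPS heptads whose phosphorylation changes as the polymerase initiates, elongates and terminates. Per the labels, the strains named Y1F, S2A, S2A-S7A and T4A carry 29 heptads with the named amino acid changes. The strains named ALT-P3A, ALT-S5A and ALT-P6A also carry 29 heptads, and the labels do not expand the prefix ALT. WT18 carries 18 heptads of the unchanged sequence. All were compared with a strain with 29 unchanged heptads, which was measured as control set 1 and again as control set 2. Cells grew at 30 °C in rich YES medium. The 31 libraries form 10 groups of 3 libraries, except WT18, which has 4: 2 new ones and 2 earlier ones of opposite mating type and with other auxotrophic markers. Those 2 and the T4A libraries are re-analysed from earlier series and were sequenced on other instruments. The 2 earlier WT18 libraries also had another RNA purification and library kit. Total counts ran from 15.2 M to 35.8 M per library, with a median of 22.8 M. Each level is given as CPM (counts scaled to the library total) ± SD and each log2 fold change ± SE, with n = 3 libraries per group unless stated, and adjusted p-values come from edgeR's quasi-likelihood test.

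The rpb1 transcript, the product of the mutated gene, differed between the groups. Its mean level with all libraries scaled together was 166 ± 10.4 CPM in control set 1, 84 ± 5.13 in Y1F, 58.8 ± 6.69 in S2A and 180 ± 6.28 in S2A-S7A. It was 473 ± 40 CPM in control set 2, 62.8 ± 22.2 in T4A, 94.3 ± 6.19 in ALT-P3A, 96 ± 11.7 in ALT-S5A, 70.4 ± 3.57 in ALT-P6A and 229 ± 49.7 in WT18 (n = 4). Counts per gene do not show the heptad codons, so they do not check which allele a library carries.

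**Figure D1:**
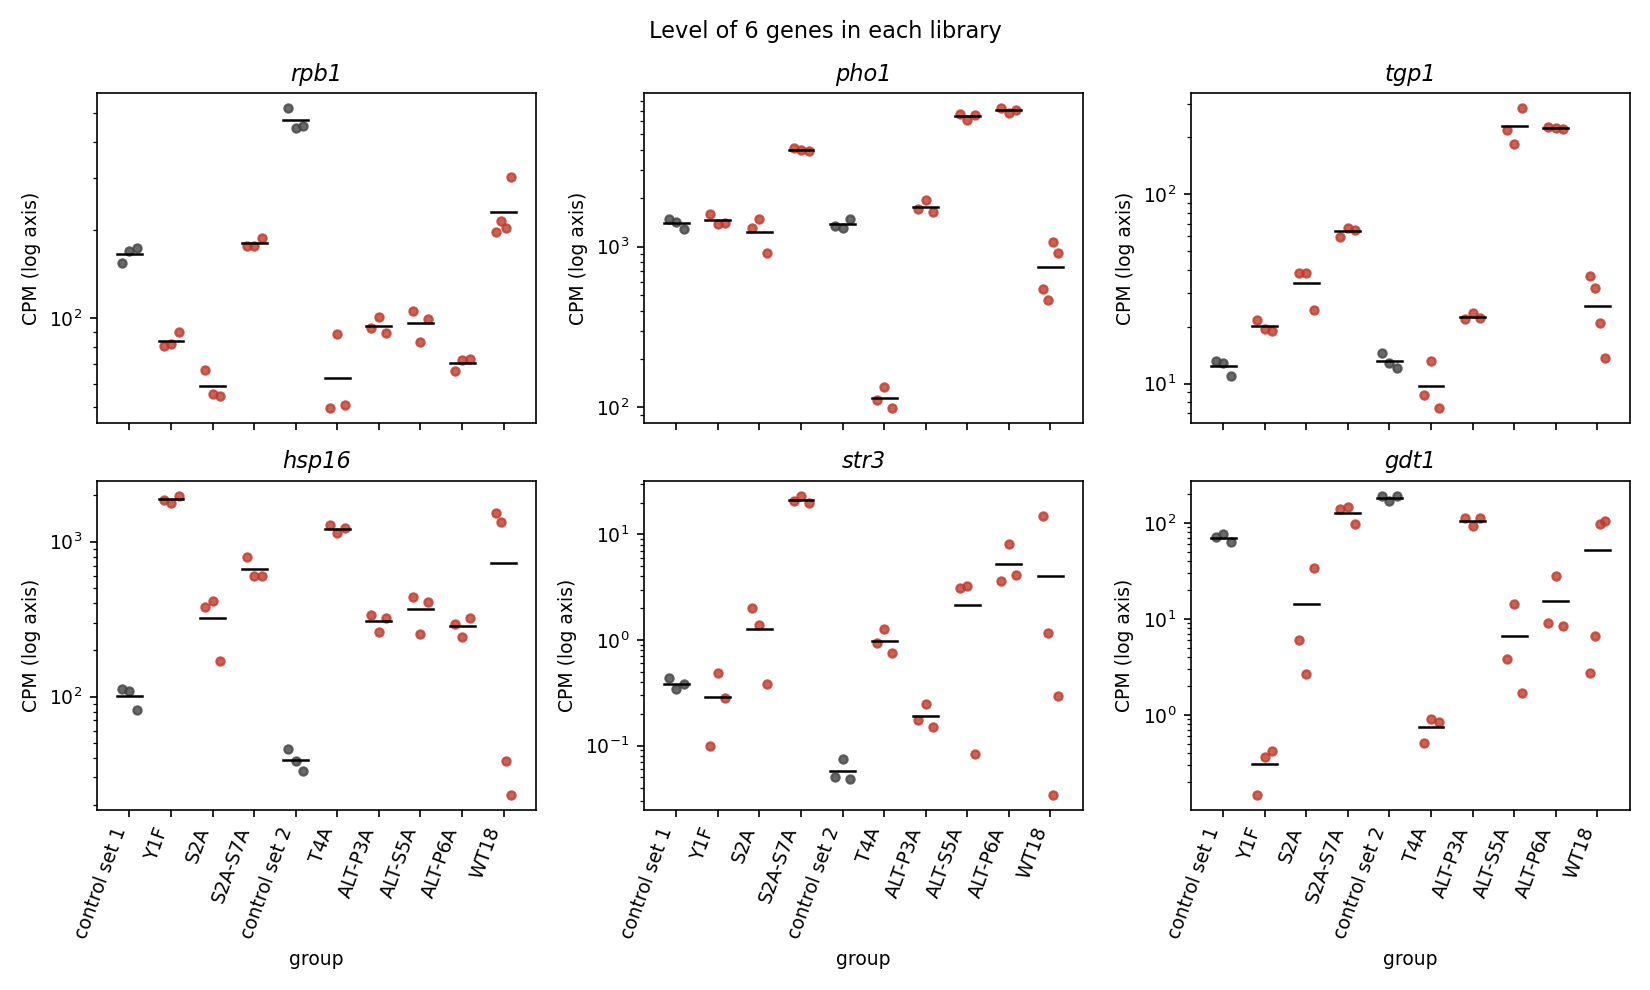
CPM of 6 genes in every library (points; log axis) and the mean of each group (line), control sets in grey and CTD alleles in red. The pho1 level averaged 115 CPM in T4A and 7030 CPM in ALT-P6A, against 1390 and 1380 CPM in the control sets, and hsp16 was high in 2 and low in 2 WT18 libraries.

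The control sets carry 1 strain label, which the counts do not check. Genes of early sexual differentiation were lower in set 2: ste11 (SPBC32C12.02), the transcription factor that starts mating and meiosis (log2 fold change -2.57 ± 0.08, adjusted p = 8.1e-07), mei2 (SPAC27D7.03c), the RNA-binding protein that drives meiosis (-2.60 ± 0.13), and the mating MAP kinase gene spk1 (SPAC31G5.09c; -1.92 ± 0.10). Of 14 measured mating genes, 2 rose and 8 fell (camera adjusted p = 0.03, adjusted p = 0.99 with an estimated correlation). The gluconeogenic gene fbp1 (SPBC1198.14c) was also lower (-2.1 ± 0.24), while rpb1 (SPBC28F2.12; 1.56 ± 0.09), the high-affinity glucose transporter gene ght5 (SPCC1235.14; 2.14 ± 0.22) and the flocculin gene pfl7 (SPBC359.04c; 2.83 ± 0.18) were higher in set 2. Large differences were also seen for SPBPB2B2.06c (3.85 ± 0.27), SPBPB10D8.02c (3.33 ± 0.29) and SPCC1235.18 (3.16 ± 0.24), higher in set 2, and for SPBPB21E7.04c (-6.55 ± 0.86) and SPCC737.04 (-6.20 ± 0.39), lower in set 2. The 137 ribosomal protein genes had a median of -0.14, with 2 higher and 52 lower (adjusted p = 2.8e-05, adjusted p = 0.99 with an estimated correlation). Of 16 ribosome biogenesis genes 1 was higher and 8 were lower (adjusted p = 0.041, adjusted p = 0.99 with an estimated correlation). Of 14 glucose-repressed and hexose transporter genes 8 were higher and 4 lower in set 2 (camera adjusted p = 0.11). Of 13 flocculation genes 5 were higher and 2 lower (camera adjusted p = 0.39). In all, 304 genes were called higher and 233 lower of 6043 tested, but 289 and 412 without control set 2 replicate 5.

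Each allele was therefore compared with either control set, the set that the labels name for it being the main reference. For T4A, the ALT alleles and WT18 there is a further reference, the authors' deposited tables, because their control means could not be rebuilt from the 3 count columns assigned to control set 2. Named genes that turned direction with another reference are given with their value there.

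**Figure D2:**
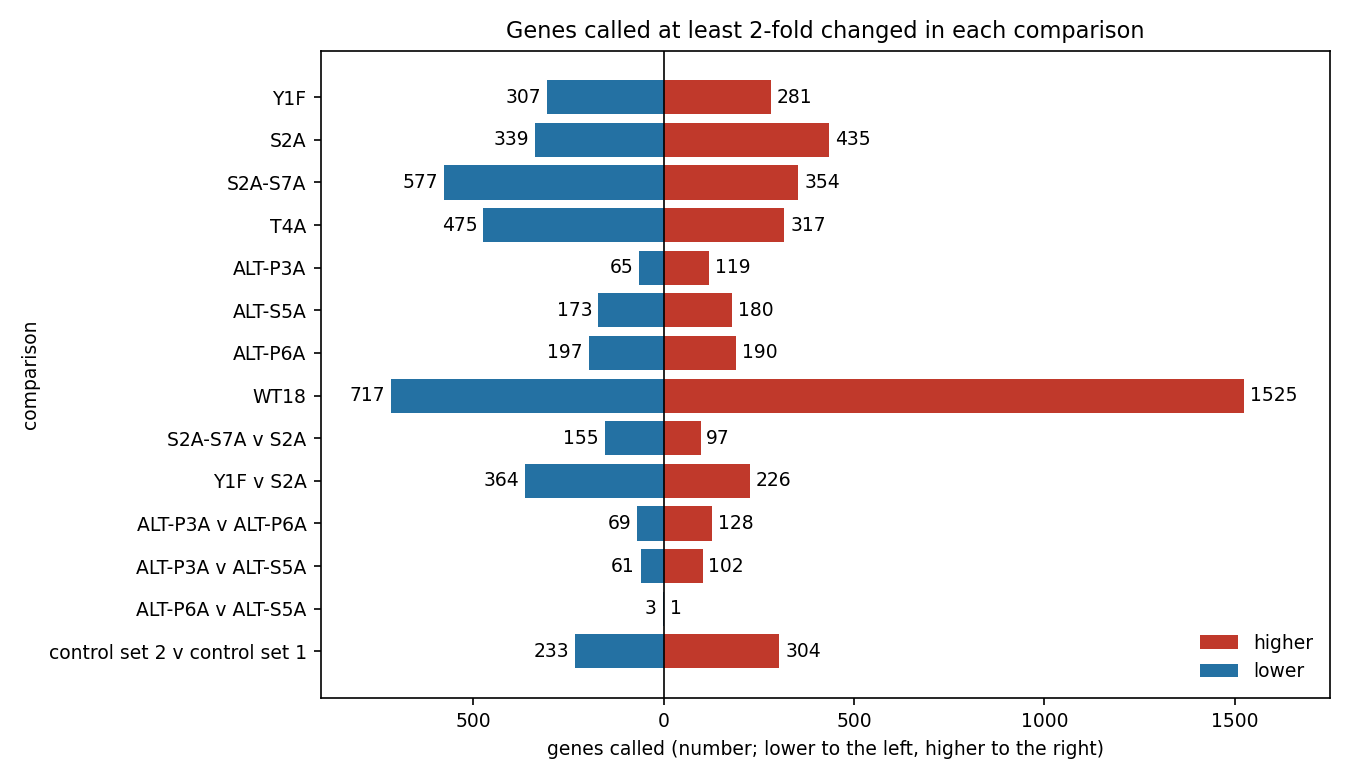
Number of genes called at least 2-fold higher (right, red) or lower (left, blue) at an adjusted p under 0.05 in each of the 14 comparisons. The counts run from 4 genes for ALT-P6A against ALT-S5A to 2242 for WT18 against control set 2.

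The Y1F comparison asks which genes need the hydroxyl group of tyrosine at the first heptad position. Stress and chaperone genes rose: hsp16 (SPBC3E7.02c), a small heat shock protein gene, went from 95.6 ± 15.7 to 1760 ± 87.8 CPM (log2 fold change 4.2 ± 0.12, adjusted p = 2.4e-11). The Hsp70 gene ssa1 (SPAC13G7.02c; 3.09 ± 0.13) and the disaggregase gene hsp104 (SPBC16D10.08c; 2.22 ± 0.08) rose too. Of 15 chaperone genes 12 rose and 2 fell, as many as adjusted over the list alone (camera adjusted p = 2.3e-06, adjusted p = 0.48 with an estimated correlation). Of 15 core stress genes, 11 rose and 0 fell, also 11 and 0 adjusted over the list alone (adjusted p = 1.5e-07, adjusted p = 0.48 with an estimated correlation). Among them were the trehalose synthase gene tps1 (SPAC328.03; 1.69 ± 0.08), the pyridoxal reductase gene plr1 (SPAC9E9.11; 1.88 ± 0.13) and the metallothionein gene zym1 (SPAC22H10.13; 1.98 ± 0.11). Antioxidant and drug-response genes followed: 8 of 11 rose and 1 fell (9 and 1 adjusted over the list alone), led by the transporter gene caf5 (SPBC609.04; 3.49 ± 0.12), the glutathione transferase gene gst2 (SPCC965.07c; 3.03 ± 0.19) and the sulfiredoxin gene srx1 (SPBC106.02c; 2.47 ± 0.13), at an adjusted p = 8.1e-05, adjusted p = 0.48 with an estimated correlation. Further large rises were ddr48 (SPAC23H3.15c; 4.33 ± 0.15), SPAC27D7.09c (4.22 ± 0.18), mug108 (SPAC29A4.12c; 3.83 ± 0.19) and lsd90 (SPBC16E9.16c; 2.91 ± 0.11).

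Genes of growth and of mating fell in Y1F. Of 137 ribosomal protein genes 0 rose and 104 fell (109 adjusted over the list alone), by a median of -0.31 (adjusted p = 8.9e-15, adjusted p = 0.55 with an estimated correlation). Of 16 ribosome biogenesis genes 13 fell and 0 rose, such as the fibrillarin gene fib1 (SPBC2D10.10c; -1.03 ± 0.07), at an adjusted p = 1.8e-05, adjusted p = 0.48 with an estimated correlation. Of 12 polymerase II subunit genes 7 fell and 0 rose, with rpb1 at -1.0 ± 0.08 (adjusted p = 0.034, adjusted p = 0.48 with an estimated correlation). The mating genes ste11 (-2.85 ± 0.08), mei2 (-1.84 ± 0.11) and spk1 (-1.83 ± 0.09) were among the 10 of 14 that fell, while 1 rose (adjusted p = 0.0044, adjusted p = 0.48 with an estimated correlation). The Golgi ion antiporter gene gdt1 (SPAC186.05c) was almost silent, at 0.293 ± 0.137 against 66.4 ± 6.61 CPM (log2 fold change -7.78 ± 0.21, adjusted p = 2.4e-11), and SPAC750.01 (-6.63 ± 0.27), SPAC977.18 (-4.15 ± 0.49) and the peptide N-glycanase gene ngl1 (SPBC1709.14; -3.27 ± 0.27) also fell. The phosphate transporter gene pho84 (SPBC8E4.01c) fell (-1.42 ± 0.08), while the acid phosphatase gene pho1 (SPBP4G3.02) stood at 0.05 ± 0.09 (adjusted p = 0.61). Of 8 cell separation genes 4 rose and 0 fell (adjusted p = 0.049, adjusted p = 0.55 with an estimated correlation). Among annotated antisense RNAs cwf28-antisense-1 (SPNCRNA.1653; 3.89 ± 0.13) and ckk2-antisense-1 (SPNCRNA.1271; 2.98 ± 0.18) were higher and cbp6-antisense-1 (SPNCRNA.1378) was lower (-3.98 ± 0.35).

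In all, 281 genes rose and 307 fell at least 2-fold of 6006 tested, and 178 and 125 of them did so against control set 2 as well. Against control set 2, 14 chaperone genes rose and 0 fell, 69 ribosomal protein genes fell and 19 rose, and the mating genes had a median of 0.03. There ste11 stood at -0.26, mei2 at 0.78, spk1 at 0.11, fib1 at -0.50 and pho84 at -0.73, and SPCC737.04 (-2.94 ± 0.26 here), SPBPB21E7.04c (-3.61 ± 0.57) and cbp6-antisense-1 turned to rises. Their values there were 3.27, 2.94 and 1.03. Smaller changes there were those of SPAC750.01 (-3.44), SPAC977.18 (-1.03), SPAC27D7.09c (2.99) and gst2 (2.1).

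S2A replaces the serine at heptad position 2, a mark of elongating polymerase, with alanine. The mating programme was lower: mei2 went from 134 ± 18.6 to 5.36 ± 0.724 CPM (log2 fold change -4.65 ± 0.15, adjusted p = 6.8e-08), ste11 fell (-3.51 ± 0.25), and so did the mating regulator gene map1 (SPAC11E3.06; -3.23 ± 0.31), the G protein gene gpa1 (SPBC24C6.06; -2.17 ± 0.12), spk1 (-2.86 ± 0.12) and the adaptor gene ste4 (SPAC1565.04c; -2.46 ± 0.24). Of 13 measured mating genes 1 rose and 8 fell, as many as adjusted over the list alone, by a median of -0.82 (camera adjusted p = 0.00041, adjusted p = 0.55 with an estimated correlation). This was the only list of 24 past the threshold with the preset correlation. The nitrogen-regulated permease gene isp5 (SPAC1039.09; -2.19 ± 0.23) and the capping methyltransferase gene pcm1 (SPCC330.10; -1.47 ± 0.20) also fell.

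Among the rises, thiamine-repressed nmt1 (SPCC1223.02) went from 0.747 ± 0.269 to 9.15 ± 0.634 CPM (log2 fold change 3.59 ± 0.27, adjusted p = 8.1e-06), the subtelomeric RecQ-type helicase gene tlh2 (SPBCPT2R1.08c) rose (3.25 ± 0.40), and so did the flocculin gene pfl3 (SPBC947.04; 3.15 ± 0.13) and the invertase gene inv1 (SPCC191.11; 2.05 ± 0.18). Iron acquisition genes tended upward, with 7 of 10 higher and 2 lower, among them the iron oxidase and permease genes fio1 (SPAC1F7.08; 2.81 ± 0.42) and fip1 (SPAC1F7.07c; 2.26 ± 0.37) and the siderophore transporter gene str1 (SPBC4F6.09; 1.49 ± 0.29), but the list did not pass (adjusted p = 0.21). The glycerophosphodiester transporter gene tgp1 (SPBC1271.09) rose (1.44 ± 0.20), while pho84 fell (-0.59 ± 0.11) and pho1 did not pass (-0.18 ± 0.15). Other large rises were SPAPB18E9.04c (2.93 ± 0.10), the peptide transporter gene opt3 (SPCC1840.12; 2.61 ± 0.21) and the predicted nucleotidase genes SPBPB2B2.06c (3.67 ± 0.47) and SPAC1039.02 (2.76 ± 0.23). Large falls were SPAC750.01 (-7.52 ± 0.31) and SPCC330.03c (-3.13 ± 0.30).

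Non-coding RNAs made up most of the rises: 282 of 435 called rises and 155 of 339 falls were long non-coding RNAs. This class also made up 183 of the 304 genes called higher in control set 2 than in control set 1, and 74 of the 233 lower. Part of the excess among the rises may therefore come from control set 1. The class was not counted for S2A against control set 2. The antisense RNAs pck1-antisense-1 (SPNCRNA.818; 5.83 ± 0.35) and taf73-antisense-1 (SPNCRNA.1577; 5.08 ± 0.36) rose, and the intergenic omt3 (SPNCRNA.130) went from 26.5 ± 1.82 to 0.067 ± 0.0813 CPM. As a class, long non-coding RNAs had a median of 0.23 over 989 measured (adjusted p = 0.0016, and adjusted p = 0.38 with an estimated correlation). In all, 435 genes rose and 339 fell at least 2-fold of 6016 tested, and 292 and 180 of them did so against control set 2 as well. Against control set 2, ste11 stood at -0.95, mei2 at -2.06, spk1 at -0.95, ste4 at -0.68, SPAC1039.02 at 0.58, SPCC330.03c at -0.55, SPBPB2B2.06c at -0.19, isp5 at 0.10 and pho84 at 0.08, and SPCC737.04 (-3.99 ± 0.45 here) and SPBPB21E7.04c (-3.39 ± 0.67) turned to rises (2.19 and 3.14 there). The changes of map1 (-1.26), pfl3 (1.82), SPAC750.01 (-4.36) and the antisense RNAs of pck1 (3.69) and taf73 (3.01) were smaller there.

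S2A-S7A combines the alanine change at position 2 with the same change at position 7. Iron acquisition stood out: str3 (SPAC1F8.03c), a siderophore-iron transporter gene, went from 0.34 ± 0.0379 to 19.1 ± 1.43 CPM (log2 fold change 5.79 ± 0.20, adjusted p = 1.1e-06), and the heme acquisition gene shu1 (SPAC1F8.02c; 5.64 ± 0.26), fio1 (2.60 ± 0.18), fip1 (2.44 ± 0.13), str1 (2.23 ± 0.15) and the ferric reductase gene frp1 (SPBC1683.09c; 2.37 ± 0.17) rose with it. Of 12 iron uptake genes 10 rose and 0 fell, as many as adjusted over the list alone, by a median of 1.60 (camera adjusted p = 4e-05, adjusted p = 0.34 with an estimated correlation). All 3 phosphate genes rose, pho1 from 1230 ± 74.8 to 3620 ± 91.1 CPM (1.56 ± 0.07), tgp1 (2.40 ± 0.12) and pho84 (0.36 ± 0.07), at an adjusted p = 0.01, adjusted p = 0.46 with an estimated correlation. Thiamine genes rose in 6 of 8 cases and fell in 0 (7 and 0 adjusted over the list alone), led by nmt1 (3.71 ± 0.25), at an adjusted p = 0.0052, adjusted p = 0.51 with an estimated correlation. Chaperone genes rose in 9 of 15 cases and fell in 0, with hsp16 at 2.76 ± 0.14 and ssa1 at 1.49 ± 0.13 (adjusted p = 0.0045, adjusted p = 0.51 with an estimated correlation). Of 17 sterol and lipid genes 10 rose and 3 fell, by a median of 0.42 (adjusted p = 0.016, adjusted p = 0.65 with an estimated correlation).

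The mating genes mei2 (log2 fold change -3.31 ± 0.19, adjusted p = 7.7e-06), ste11 (-2.32 ± 0.21), ste4 (-2.85 ± 0.24) and map1 (-2.65 ± 0.27) fell, with 4 of 14 higher and 9 lower (adjusted p = 0.018, adjusted p = 0.46 with an estimated correlation). Other falls were the histone methyltransferase gene set7 (SPCC297.04c; -2.74 ± 0.25), the kelch repeat gene mde6 (SPAC15A10.10; -2.71 ± 0.48), SPAC11D3.10 (-2.52 ± 0.22) and the termination factor gene rhn1 (SPBC337.03; -1.18 ± 0.18). The invertase gene inv1 (2.18 ± 0.14), SPAPB18E9.04c (3.06 ± 0.09), SPAC1039.02 (3.17 ± 0.24) and the predicted amino acid transporter gene SPBPB2B2.01 (2.67 ± 0.14) rose, and so did the antisense RNAs cbh1-antisense-1 (SPNCRNA.990; 4.39 ± 0.25) and cwf28-antisense-1 (3.75 ± 0.15), while omt3 fell (-3.47 ± 0.26). The rpb1 level stood at 0.15 ± 0.07 (adjusted p = 0.1).

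In all, 354 genes rose and 577 fell at least 2-fold of 6006 tested, 421 of the falls in coding genes, and 200 rises and 183 falls were called against control set 2 as well. Against control set 2, 9 iron uptake genes rose and 2 fell, 3 of 3 phosphate genes rose, mei2 stood at -0.68, ste11 at 0.28, ste4 at -1.03, map1 at -0.65, omt3 at 0.13 and mde6 at -0.07, and SPCC737.04 (-3.11 ± 0.39), SPBPB21E7.04c (-2.99 ± 0.68) and cbp6-antisense-1, which fell here, turned to rises. Their values there were 3.12, 3.58 and 1.78. The rises of SPAC1039.02 (1.02) and SPBPB2B2.01 (1.66) were smaller there.

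In the direct contrast of S2A-S7A with S2A, which asks what the change at position 7 adds, str3 was higher by 4.13 ± 0.37, shu1 by 4.02 ± 0.41, frp1 by 3.19 ± 0.25, rpb1 by 1.65 ± 0.09 and pho1 by 1.74 ± 0.14. All 3 phosphate genes were higher (adjusted p = 0.00098, adjusted p = 0.48 with an estimated correlation). So were 4 of 12 iron uptake genes with 0 lower (adjusted p = 0.014, adjusted p = 0.48 with an estimated correlation). Of 17 sterol genes 11 were higher and 1 lower (adjusted p = 0.00084, adjusted p = 0.48 with an estimated correlation), and of 11 antioxidant genes 6 were higher and 0 lower (adjusted p = 0.00084, adjusted p = 0.48 with an estimated correlation). Past the threshold were also chaperone genes (5 higher and 0 lower of 15, adjusted p = 0.025, adjusted p = 0.48 with an estimated correlation), histone genes (5 higher and 0 lower of 10, adjusted p = 0.014, adjusted p = 0.48 with an estimated correlation) and nitrogen starvation genes (6 higher and 1 lower of 13, adjusted p = 0.015, adjusted p = 0.48 with an estimated correlation). So were core stress genes (8 higher and 1 lower of 15, adjusted p = 0.01, adjusted p = 0.48 with an estimated correlation), cell separation genes (3 higher and 0 lower of 8, adjusted p = 0.022, adjusted p = 0.48 with an estimated correlation) and thiamine genes (3 higher and 0 lower of 8, adjusted p = 0.022, adjusted p = 0.48 with an estimated correlation). The largest coding differences were the rises of SPAC186.06 (5.77 ± 0.53) and SPAC750.01 (5.12 ± 0.72) and the falls of the chromatin remodeller gene vps71 (SPBC29A3.05; -1.65 ± 0.34), SPBC2A9.14 (-1.56 ± 0.19) and the splicing gene frg1 (SPBP23A10.12; -1.51 ± 0.20). The contrast called 97 genes higher and 155 lower. Without S2A replicate 1 it called 398 genes and without S2A replicate 3 it called 167, against 252 with all libraries. Without S2A replicate 3 the genes called higher and lower were 88 and 79. Across 5109 genes the fold changes of the 2 alleles against control set 1 had r = 0.77, against 0.5 for simulated unchanged groups, with a covariance of 0.335 against 0.0125. They shared 278 rises and 228 falls, where independent lists would share 23.6 and 32.6, and part of that excess may come from the shared controls, which are too few to split.

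T4A replaces the threonine at position 4 with alanine. Phosphate acquisition fell: pho1, the secreted acid phosphatase gene, went from 1380 ± 90 to 111 ± 15.3 CPM (log2 fold change -3.64 ± 0.14, adjusted p = 1.9e-07) and pho84 from 1050 ± 55.6 to 126 ± 11.2 CPM (-3.05 ± 0.11), while tgp1 stood at -0.49 ± 0.23 (adjusted p = 0.11). Of 3 phosphate genes 2 fell and 0 rose, as many as adjusted over the list alone (camera adjusted p = 0.0032, adjusted p = 0.7 with an estimated correlation). Chaperone genes rose in 10 of 15 cases and fell in 0, led by hsp16 (4.91 ± 0.16) and ssa1 (2.58 ± 0.17), at an adjusted p = 2.3e-05, adjusted p = 0.7 with an estimated correlation. Core stress genes rose in 11 of 15 cases and fell in 2 (adjusted p = 0.0017, adjusted p = 0.7 with an estimated correlation). Antioxidant genes rose in 8 of 11 and fell in 0, with srx1 at 2.78 ± 0.21 and gst2 at 2.13 ± 0.19 (adjusted p = 0.0015, adjusted p = 0.7 with an estimated correlation). The aldehyde dehydrogenase gene atd1 (SPAC9E9.09c; 3.48 ± 0.17) and SPAC27D7.09c (3.28 ± 0.17) rose as well. Iron uptake genes rose in 8 of 11 cases and fell in 2, with fio1 at 3.19 ± 0.24, str1 at 2.94 ± 0.20 and fip1 at 2.16 ± 0.20 (adjusted p = 0.0065, adjusted p = 0.7 with an estimated correlation).

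The Golgi antiporter gene gdt1 fell from 183 ± 11.3 to 0.728 ± 0.2 CPM (log2 fold change -7.97 ± 0.17, adjusted p = 2.3e-09). Other falls were the flocculin gene pfl7 (-5.81 ± 0.41), the mitochondrial elongation factor gene guf1 (SPAC1B3.04c; -4.32 ± 0.29), aes1 (SPBPB21E7.07; -3.56 ± 0.16), SPBPB10D8.01 (-3.88 ± 0.22) and pcm1 (-1.85 ± 0.21). Thiamine genes fell in 5 of 8 cases and rose in 0 (adjusted p = 0.029, adjusted p = 0.7 with an estimated correlation). In control set 2 itself 3 of them were higher and 0 lower than in control set 1. Meiotic transcripts, which vegetative cells normally destroy, rose in 6 of 10 cases and fell in 1, such as ssm4 (SPAC27D7.13c; 2.56 ± 0.40), at an adjusted p = 0.029, adjusted p = 0.7 with an estimated correlation. Among non-coding RNAs SPCC1919.05-antisense-1 (SPNCRNA.1273; 4.59 ± 0.18) and orc1-antisense-1 (SPNCRNA.1529; 4.24 ± 0.24) rose, and 261 of 475 called falls were long non-coding RNAs against 95 of 317 rises. This class also made up 183 of the 304 genes called higher in control set 2 than in control set 1, and 74 of the 233 lower. Part of the excess among the falls may therefore come from control set 2. The class was not counted for T4A against control set 1.

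In all, 317 genes rose and 475 fell at least 2-fold of 6018 tested, and 107 and 131 did so with all 3 references, pho1, pho84, hsp16, atd1, fio1, str1, gdt1, pfl7 and guf1 among them. The counts were 489 and 451 without control set 2 replicate 5, so which direction held more genes hung on that library. Ribosomal protein genes rose in 45 of 137 cases and fell in 2 (adjusted p = 2.3e-05, adjusted p = 0.72 with an estimated correlation). Against control set 1, 11 rose and 15 fell, and SPBPB21E7.04c and SPCC737.04, which rose here, turned to falls there (-3.28 and -3.03). Both also fell in the authors' deposited table (-5.83 and -4.21). Other changes kept their direction but were smaller against control set 1: pfl7 (-2.98), SPBPB10D8.01 (-1.65), aes1 (-2.19), hsp16 (3.58) and gdt1 (-6.54). The authors' deposited table gives pfl7 at -2.40, SPBPB10D8.01 at -1.23, hsp16 at 3.28, gdt1 at -6.65 and ssm4 at 1.47.

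ALT-P3A changes the proline at position 3. With all libraries it had the fewest called genes of the 8 alleles, but without control set 2 replicate 5 it had 475 against 453 in ALT-S5A, and with no minimum fold 2608 against 2007. The chaperone gene hsp16 went from 41.6 ± 6.97 to 325 ± 44.7 CPM (log2 fold change 2.97 ± 0.13, adjusted p = 1.4e-06), atd1 rose (1.68 ± 0.08), and so did SPAPB18E9.04c (1.95 ± 0.09) and the sulfiredoxin gene srx1 (1.26 ± 0.14). Of 15 chaperone genes 10 rose and 1 fell (camera adjusted p = 0.0077, adjusted p = 0.56 with an estimated correlation). Of 15 core stress genes 9 rose and 3 fell (adjusted p = 0.028, adjusted p = 0.56 with an estimated correlation). Of 11 antioxidant genes 7 rose and 0 fell (adjusted p = 0.015, adjusted p = 0.56 with an estimated correlation). The phosphate genes pho1 (0.35 ± 0.08), tgp1 (0.76 ± 0.13) and pho84 (0.18 ± 0.06) all rose, by less than 2-fold (adjusted p = 0.049, adjusted p = 0.56 with an estimated correlation), but pho84 did not pass without any 1 of the 6 libraries and stood at -0.53 against control set 1. In the authors' deposited table pho84 stood at 0.01, pho1 at 0.81 and tgp1 at 1.18.

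Lower genes were the glucose transporter gene ght5, from 768 ± 153 to 140 ± 9.13 CPM (log2 fold change -2.46 ± 0.13, adjusted p = 2.6e-06), pfl7 (-3.91 ± 0.14), rpb1 (-2.34 ± 0.08), SPBPB10D8.01 (-2.02 ± 0.12) and the sterol synthesis genes erg1 (SPBC713.12; -1.30 ± 0.07) and erg31 (SPAC1687.16c; -1.41 ± 0.06). Of 17 sterol genes 8 fell and 0 rose (adjusted p = 0.01, adjusted p = 0.56 with an estimated correlation). Of 8 thiamine genes 5 fell and 0 rose (adjusted p = 0.028, adjusted p = 0.56 with an estimated correlation). Of 15 iron-using proteins 7 fell and 1 rose (adjusted p = 0.049, adjusted p = 0.56 with an estimated correlation). Glucose-repressed and hexose transporter genes fell in 8 of 14 cases and rose in 1 (adjusted p = 0.0077, adjusted p = 0.56 with an estimated correlation). Flocculation genes fell in 7 of 13 cases and rose in 1 (adjusted p = 0.028, adjusted p = 0.56 with an estimated correlation). In control set 2 itself, 8 of the glucose-related genes were higher and 4 lower than in control set 1. Of the flocculation genes 5 were higher and 2 lower there. Thiamine genes were higher there in 3 cases and lower in 0, and sterol genes in 6 and 2. Chaperone genes were higher in 3 and lower in 6 cases, and so were core stress genes. Antioxidant genes had 3 higher and 3 lower, iron-using proteins 3 and 4, and phosphate genes 0 and 1. Ribosomal protein genes fell in 23 of 137 cases with 9 higher (adjusted p = 0.028, adjusted p = 0.68 with an estimated correlation). The antisense RNAs cwf28-antisense-1 (1.90 ± 0.13) and ckk2-antisense-1 (1.65 ± 0.16) rose.

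The called genes numbered 119 rises and 65 falls of 6081 tested, and 415 and 60 without control set 2 replicate 5. Only 29 rises and 14 falls held with all 3 references, hsp16, atd1, SPAPB18E9.04c and the antisense RNAs of cwf28 and ckk2 among them, while against control set 1 ght5 stood at -0.35, pfl7 at -1.11, rpb1 at -0.81 and SPBPB10D8.01 at 0.18, and SPBPB2B2.06c and SPAC2H10.01, which fell here (-1.96 ± 0.14 and -1.92 ± 0.13), turned to rises. These rises were 1.85 and 0.73, and erg31 stood at -0.34 there. Of the changes that held, the hsp16 rise was 1.62 and that of SPAPB18E9.04c 1.33 there, and the authors' deposited table gives 1.29 and 1.05. With all groups of the control set in 1 fit 123 genes were called, and hsp16, ckk2-antisense-1, pho1, tgp1 and pho84 did not pass. That fit also held the WT18 libraries, in which hsp16 ran from 23.1 to 1530 CPM. Whether their spread cost these calls was not tested. In the authors' deposited table ght5 stood at 1.01, pfl7 at -0.55, rpb1 at -0.67, erg31 at -0.53, SPBPB10D8.01 at 0.58, SPBPB2B2.06c at 2.38 and SPAC2H10.01 at 0.76.

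ALT-S5A changes the serine at position 5, a mark of early elongation. Phosphate acquisition rose: tgp1 went from 13.5 ± 1.52 to 228 ± 49.4 CPM (log2 fold change 4.08 ± 0.16, adjusted p = 1.1e-08), pho1 from 1410 ± 93.8 to 6470 ± 344 CPM (2.19 ± 0.09), and pho84 rose (1.35 ± 0.09). All 3 phosphate genes rose, as many as adjusted over the list alone (camera adjusted p = 1e-05, adjusted p = 0.6 with an estimated correlation), and 3 of 3 rose against control set 1, with pho84 at 0.68. Chaperone genes rose in 10 of 15 cases and fell in 0 (11 and 0 adjusted over the list alone), with hsp16 at 3.20 ± 0.20 and ssa1 at 1.68 ± 0.14 (adjusted p = 1.1e-06, adjusted p = 0.6 with an estimated correlation). Antioxidant genes rose in 9 of 11 cases and fell in 1, with caf5 at 1.90 ± 0.14 and the brefeldin resistance gene obr1 (SPAC3C7.14c) at 1.60 ± 0.09 (adjusted p = 1.2e-05, adjusted p = 0.6 with an estimated correlation). Core stress genes rose in 8 of 15 cases and fell in 2 (adjusted p = 0.0039, adjusted p = 0.68 with an estimated correlation). Histone genes rose in 6 of 10 cases and fell in 0, such as hhf2 (SPBC8D2.03c; 0.81 ± 0.12) and hta1 (SPCC622.08c; 0.55 ± 0.11), at an adjusted p = 0.0017, adjusted p = 0.67 with an estimated correlation. The hta1 value in the authors' deposited table was 0.18, which did not pass. The kinase gene ppk31 (SPBC725.06c; 2.84 ± 0.25) and atd1 (2.19 ± 0.10) rose with all 3 references, and the uracil-regulated urg1 (SPAC1002.19) rose against either control set (2.88 ± 0.23 here) but stood at -1.32 in the authors' deposited table.

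Among the falls, SPBPB10D8.02c, a predicted arylsulfatase gene (-5.57 ± 0.31), pfl7 (-5.26 ± 0.21), gdt1 (-4.76 ± 0.47), the predicted cysteine transporter gene SPBPB10D8.01 (-3.66 ± 0.21) and SPBPB2B2.01 (-2.99 ± 0.37) all fell with every reference, but by less with the others. Against control set 1 they stood at -2.23, -2.42, -3.34, -1.42 and -1.94, and in the authors' deposited table at -1.95, -1.86, -3.52, -1.01 and -2.13. Flocculation genes fell in 8 of 13 cases and rose in 1 (adjusted p = 0.003, adjusted p = 0.67 with an estimated correlation), but 5 of them were higher and 2 lower in control set 2 than in set 1. The sterol desaturase gene erg31 fell (-1.90 ± 0.11), but stood at -0.79 against control set 1 and at -0.98 in the authors' deposited table. Ribosomal protein genes rose in 14 of 137 cases and fell in 0 (adjusted p = 0.0028, adjusted p = 0.81 with an estimated correlation). Against control set 1, 6 rose and 34 fell. Of the non-coding RNAs, SPNCRNA.1278 rose (2.03 ± 0.20; 0.98 against control set 1) and pep3-antisense-1 (SPNCRNA.1277) fell (-2.82 ± 0.19; -0.68 against control set 1 and 0.54 in the authors' deposited table). The intergenic omt3 rose here (2.41 ± 0.41) and turned to a fall against control set 1 (-1.15) and in the authors' deposited table (-1.85).

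In all, 180 genes rose and 173 fell at least 2-fold of 6086 tested, and 66 and 67 did so with all 3 references. The counts were 280 and 173 without control set 2 replicate 5. The rpb1 fall (-2.34 ± 0.12) was -0.77 against control set 1 and -0.62 in the authors' deposited table. The rises of hsp16 (1.89) and urg1 (1.96) were smaller against control set 1, with hsp16 at 1.57 in the authors' deposited table. With all groups of the control set in 1 fit ssa1, hta1 and omt3 did not pass.

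ALT-P6A changes the proline at position 6, and the phosphate genes rose as in ALT-S5A. The pho1 level went from 1410 ± 101 to 7180 ± 251 CPM (log2 fold change 2.35 ± 0.08, adjusted p = 8.8e-08), tgp1 rose (4.09 ± 0.07), and so did pho84 (1.41 ± 0.06), so that all 3 phosphate genes rose (camera adjusted p = 0.00014, adjusted p = 0.38 with an estimated correlation). Histone genes rose in 9 of 10 cases and fell in 0 (10 and 0 adjusted over the list alone), such as hhf2 (0.73 ± 0.07) and hta1 (0.66 ± 0.08), at an adjusted p = 0.00014, adjusted p = 0.62 with an estimated correlation, and in 7 cases against control set 1. Chaperone genes rose in 8 of 15 cases and fell in 0, with hsp16 at 2.88 ± 0.13 and ssa1 at 1.33 ± 0.07 (adjusted p = 0.00014, adjusted p = 0.62 with an estimated correlation). Antioxidant genes rose in 8 of 11 cases and fell in 2, led by caf5 (2.1 ± 0.09), at an adjusted p = 0.0029, adjusted p = 0.63 with an estimated correlation. Meiotic transcripts rose in 8 of 13 cases and fell in 1, with the meiotic coiled-coil protein gene mcp7 (SPAC13A11.03) at 1.71 ± 0.24 (adjusted p = 0.015, adjusted p = 0.62 with an estimated correlation). The iron genes fio1 (2.11 ± 0.16) and fip1 (1.57 ± 0.09), the kinase gene ppk31 (2.69 ± 0.21), atd1 (2.17 ± 0.07) and the dehydrogenase genes SPCC663.08c (2.47 ± 0.12) and osr1 (SPCC663.06c; 2.32 ± 0.12) rose as well.

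Among the falls were again SPBPB10D8.02c (-5.20 ± 0.28), pfl7 (-5.15 ± 0.16), SPBPB10D8.01 (-3.63 ± 0.12), gdt1 (-3.59 ± 0.37) and SPBPB2B2.01 (-3.50 ± 0.18), each with all 3 references but by less with the others. Against control set 1 they stood at -1.89, -2.34, -1.42, -2.18 and -2.49, and in the authors' deposited table at -1.59, -1.80, -1.02, -2.33 and -2.65. The pho84 rise was 0.70 against control set 1, and mcp7 stood at 0.91 in the authors' deposited table. The hsp16 rise was 1.53 against control set 1 and 1.2 in the authors' deposited table, which gives hhf2 at 0.41 and hta1 at 0.25. Flocculation genes fell in 7 of 13 cases and rose in 2 (adjusted p = 0.015, adjusted p = 0.62 with an estimated correlation), but 5 of them were higher and 2 lower in control set 2 than in set 1. The rpb1 level fell (-2.75 ± 0.07), also against control set 1 (-1.22) and in the authors' deposited table (-1.08). Ribosomal protein genes rose in 44 of 137 cases and fell in 2 (adjusted p = 0.00021, adjusted p = 0.8 with an estimated correlation), but in 12 and 39 cases against control set 1. Of the non-coding RNAs the RNase MRP RNA mrp1 (SPNCRNA.82) rose (2.53 ± 0.18) and pep3-antisense-1 fell (-3.34 ± 0.21), by less against control set 1 (1.07 and -1.23). In the authors' deposited table they stood at 0.02 and -0.02, and omt3 (2.17 ± 0.26 here) at -2.12, with -1.42 against control set 1. In all, 190 genes rose and 197 fell at least 2-fold of 6090 tested, and 51 and 73 did so with all 3 references. The counts were 353 and 204 without control set 2 replicate 5. With all groups of the control set in 1 fit ssa1, hta1 and omt3 did not pass.

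Few genes separated ALT-P6A and ALT-S5A. The direct contrast called 4 of 6140 genes, the iron oxidase gene fio1 higher in ALT-P6A (log2 fold change 1.16 ± 0.20, adjusted p = 0.039) and the coding gene SPAC15E1.02c (-1.03 ± 0.15) and 2 non-coding RNAs lower. The 3 libraries of each allele pair by replicate number, and with that number as a block the contrast called 7 genes. Leaving out 1 library gave 1 gene (without any ALT-P6A library) to 8 genes (without ALT-S5A replicate 3), and neither named gene passed without an ALT-P6A library or ALT-S5A replicate 1. With all groups of the control set in 1 fit, which also held the WT18 libraries, the contrast called 0 genes by edgeR and neither named gene passed. Chaperone genes were lower in 1 of 15 cases (7 adjusted over the list alone, adjusted p = 2.3e-06, adjusted p = 0.75 with an estimated correlation). Core stress genes were lower in 2 of 15 (7 adjusted over the list alone, adjusted p = 6.4e-06, adjusted p = 0.75 with an estimated correlation). Iron uptake genes were higher in 2 of 12 (4 adjusted over the list alone, adjusted p = 0.00059, adjusted p = 0.75 with an estimated correlation). The fold changes against control set 2 had r = 0.93 across 5199 genes, against 0.51 for simulated unchanged groups, with a covariance of 0.22 against 0.022, and 123 rises and 141 falls were shared, where independent lists would share 5.19 and 5.59. Part of the excess may come from the shared controls, which are too few to split.

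ALT-S5A and ALT-P6A parted from ALT-P3A in their phosphate genes. These contrasts set the alleles against each other, but the control set 2 libraries were in the fit and entered its filter, scaling and spread. Against ALT-P6A, tgp1 was lower in ALT-P3A (-3.33 ± 0.06), and pho1 (-2.01 ± 0.08) and pho84 (-1.23 ± 0.06) were lower too (list adjusted p = 6.2e-07, adjusted p = 0.13 with an estimated correlation). The glucose transporter gene ght5 (-3.18 ± 0.13) and histone genes, lower in 8 of 10 cases (adjusted p = 6.1e-06, adjusted p = 0.49 with an estimated correlation), followed. Of 137 ribosomal protein genes 57 were lower (adjusted p = 1.4e-12, adjusted p = 0.58 with an estimated correlation). The genes gdt1 (2.78 ± 0.33), SPBPB2B2.06c (2.45 ± 0.18) and SPBPB2B2.01 (2.09 ± 0.16) were higher. Past the threshold were also iron uptake genes (0 higher and 5 lower of 12, adjusted p = 0.0028, adjusted p = 0.24 with an estimated correlation), chaperone genes (0 higher and 7 lower of 15, adjusted p = 0.03, adjusted p = 0.58 with an estimated correlation) and iron-using proteins (2 higher and 6 lower of 15, adjusted p = 0.023, adjusted p = 0.58 with an estimated correlation). So were antioxidant genes (1 higher and 6 lower of 11, adjusted p = 0.018, adjusted p = 0.58 with an estimated correlation), targets of the G1/S factor MBF (5 higher and 1 lower of 10, adjusted p = 0.0026, adjusted p = 0.24 with an estimated correlation) and cell separation genes (4 higher and 0 lower of 8, adjusted p = 0.023, adjusted p = 0.58 with an estimated correlation). The contrast called 128 genes higher and 69 lower in ALT-P3A, but 68 and 35 with all groups of the control set in 1 fit, where gdt1 did not pass.

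Against ALT-S5A, tgp1 (-3.34 ± 0.14), pho1 (-1.87 ± 0.08), pho84 (-1.2 ± 0.07) and urg1 (-2.57 ± 0.22) were lower in ALT-P3A (phosphate list adjusted p = 7e-07, adjusted p = 0.23 with an estimated correlation). Chaperone genes were lower in 9 of 15 cases (adjusted p = 1.6e-05, adjusted p = 0.45 with an estimated correlation). Of 137 ribosomal protein genes 47 were lower (adjusted p = 1.1e-13, adjusted p = 0.52 with an estimated correlation), while gdt1 (3.90 ± 0.44), SPAC750.01 (2.61 ± 0.49) and the kinetochore gene cnp3 (SPBC1861.01c; 2.01 ± 0.15) were higher. Past the threshold were also histone genes (0 higher and 6 lower of 10, adjusted p = 0.00018, adjusted p = 0.52 with an estimated correlation), antioxidant genes (0 higher and 5 lower of 11, adjusted p = 0.00016, adjusted p = 0.35 with an estimated correlation), iron-using proteins (1 higher and 4 lower of 15, adjusted p = 0.012, adjusted p = 0.45 with an estimated correlation) and polymerase II subunit genes (0 higher and 4 lower of 12, adjusted p = 0.031, adjusted p = 0.45 with an estimated correlation). So were targets of the G1/S factor MBF (3 higher and 1 lower of 10, adjusted p = 0.048, adjusted p = 0.53 with an estimated correlation), cell separation genes (2 higher and 0 lower of 8, adjusted p = 0.036, adjusted p = 0.53 with an estimated correlation) and flocculation genes (5 higher and 1 lower of 13, adjusted p = 0.049, adjusted p = 0.53 with an estimated correlation). The contrast called 102 genes higher and 61 lower, but 105 in all with all groups of the control set in 1 fit.

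Y1F and S2A, which share control set 1, differed in stress genes. The direct contrast found ddr48 (log2 fold change 3.70 ± 0.26, adjusted p = 7.7e-07), zym1 (3.26 ± 0.17), gst2 (2.86 ± 0.31), hsp16 (2.53 ± 0.25) and ssa1 (2.33 ± 0.16) higher in Y1F, with 12 of 15 core stress genes higher and 2 lower (adjusted p = 1.8e-06, adjusted p = 0.46 with an estimated correlation). Of 11 antioxidant genes 9 were higher and 0 lower (adjusted p = 7.2e-08, adjusted p = 0.26 with an estimated correlation). Ribosomal protein genes were lower in 99 of 137 cases (adjusted p = 3e-17, adjusted p = 0.51 with an estimated correlation). So were gdt1 (-5.50 ± 0.94), tlh2 (-5.06 ± 0.43) and SPBPB10D8.01 (-3.14 ± 0.21), and 8 of 13 flocculation genes (adjusted p = 0.0013, adjusted p = 0.26 with an estimated correlation). The mating gene mei2, lower in each of them than in control set 1, was higher in Y1F than in S2A (2.80 ± 0.14). Past the threshold were also chaperone genes (10 higher and 2 lower of 15, adjusted p = 0.00031, adjusted p = 0.46 with an estimated correlation), mating genes (7 higher and 2 lower of 14, adjusted p = 0.022, adjusted p = 0.41 with an estimated correlation) and cell separation genes (5 higher and 0 lower of 8, adjusted p = 0.0033, adjusted p = 0.46 with an estimated correlation). So were ribosome biogenesis genes (0 higher and 9 lower of 16, adjusted p = 0.0012, adjusted p = 0.26 with an estimated correlation), polymerase II subunit genes (1 higher and 7 lower of 12, adjusted p = 0.035, adjusted p = 0.41 with an estimated correlation) and thiamine genes (0 higher and 4 lower of 8, adjusted p = 0.022, adjusted p = 0.46 with an estimated correlation). The contrast called 226 genes higher and 364 lower.

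WT18 shortens the CTD to 18 heptads with no amino acid change, and it differed from control set 2 in more genes than any other allele. Of 137 ribosomal protein genes, 1 rose and 105 fell (107 adjusted over the list alone), by a median of -0.89 (camera adjusted p = 7.4e-13, adjusted p = 0.67 with an estimated correlation). Of 16 ribosome biogenesis genes 8 rose and 5 fell, by a median of 0.22 (adjusted p = 0.6). Sterol and lipid genes fell in 15 of 17 cases and rose in 0, with the HMG-CoA reductase gene hmg1 (SPCC162.09c) at -1.72 ± 0.19 and erg11 (SPAC13A11.02c) at -1.41 ± 0.16 (adjusted p = 0.00021, adjusted p = 0.67 with an estimated correlation). Iron-using proteins fell in 9 of 15 cases and rose in 1 (adjusted p = 0.035, adjusted p = 0.67 with an estimated correlation). Other falls were the homoserine kinase gene thr1 (SPBC4C3.03; -2.01 ± 0.16), the amino acid transporter gene aat1 (SPBC359.03c; -2.02 ± 0.14), the vacuolar transporter chaperone gene nrf1 (SPBC21B10.04c; -1.99 ± 0.21) and the predicted transcription factor gene sfp1 (SPAC16.05c; -2.04 ± 0.22). In the authors' deposited table thr1 stood at -1.69, aat1 at -1.09, nrf1 at -1.37 and sfp1 at -2.26.

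Meiotic transcripts, normally removed in vegetative cells, rose in 12 of 13 cases and fell in 0, as many as adjusted over the list alone, by a median of 2.78 (adjusted p = 0.0012, adjusted p = 0.7 with an estimated correlation). The meiotic RNA-binding protein gene spo5 (SPBC29A10.02) went from 0.416 ± 0.0554 to 7.92 ± 1.19 CPM (n = 4, log2 fold change 4.24 ± 0.30, adjusted p = 0.00017), and ssm4 (4.21 ± 0.49) and mcp7 (4.10 ± 0.61) rose with all 3 references. Their rises were smaller in the authors' deposited table (2.92, 3.04 and 3.29). The predicted flavin oxidoreductase gene SPBC23G7.10c went from 0.124 ± 0.00923 to 12.1 ± 5.03 CPM, and all 4 libraries lay above every control library. Rises that varied widely among the 4 libraries were ddr48, at 68.9 ± 75.2 CPM (4.81 ± 1.19), mug108 (4.60 ± 1.52; 3.61 against control set 1) and the glyceraldehyde phosphate dehydrogenase gene gpd3 (SPBC354.12; 3.55 ± 0.92). Of these, ddr48 stood at 1.43 and mug108 at 1.97 in the authors' deposited table, and neither passed there. The mug108 level was higher by 5.03 ± 0.6 (log2) in the new than in the earlier WT18 libraries. The long non-coding RNA SPNCRNA.1511 rose (5.70 ± 1.40), at 63.1 ± 69.1 CPM. The phosphate gene pho1 fell (-0.88 ± 0.27), but not past the threshold without control set 2 replicate 6 (-0.82) or in the authors' deposited table (-0.40). The tgp1 rise (1.00 ± 0.34) was under it without WT18 replicate 1 (0.77) or 2 (0.87) or any control library (0.94 to 1.05), and that of mug108 without any control library (4.31 to 4.78). Both phosphate genes differed by pair. With all libraries scaled together, pho1 was 545 and 462 CPM in the new and 1070 and 911 CPM in the earlier pair, against 1300 to 1490 in control set 2. The tgp1 levels were 36.9 and 31.8 CPM and 20.9 and 13.7 CPM, against 12.1 to 14.5.

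The called genes numbered 1525 rises and 717 falls of 6149 tested, and 631 and 218 did so with all 3 references. With both control sets together as control the counts were 1500 rises and 356 falls. Among coding genes the fold change ran against the expression level (rank correlation -0.44). The 2 new libraries stood apart from the 2 earlier ones, with 658 genes called higher and 142 lower in them. Small nuclear and nucleolar RNAs made up 0.159% and 0.0994% of counts in the new pair, against 0.0229% and 0.0139% in the earlier pair and 0.0127% to 0.0141% in control set 2. With no control library in common, the pairs called 748 genes in the same direction and 111 in opposite ones (new pair against control set 1), where independent lists would share 339 and 272. Against control set 1, 123 ribosomal protein genes fell and 11 of 13 meiotic transcripts rose, while pfl7, which fell here (-2.95 ± 0.38), stood at -0.19 and rpb1 (-1.03 ± 0.16 here) at 0.46. In the authors' deposited table pfl7 stood at 0.42 and rpb1 at 0.64.

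The phosphate genes separated the alleles in tests of 1 effect against another. The T4A effect on pho1 minus that of ALT-S5A was -5.81 ± 0.25 (adjusted p = 1.8e-15) and minus that of ALT-P6A was -5.94 ± 0.25 (adjusted p = 9.3e-16), and for tgp1 the difference from ALT-P6A was -4.53 ± 0.27 (adjusted p = 4.1e-12). Between ALT-S5A and ALT-P6A the pho1 effects differed by -0.12 ± 0.20 (adjusted p = 1). Among the 28 pairs of alleles, Y1F and T4A, which share no control library, had r = 0.5 across 5090 genes and shared 118 rises and 113 falls, where independent lists would share 13.8 and 20.8, and 34 genes went opposite ways. S2A-S7A and WT18 had r = -0.43 across 5095 genes, with 361 genes called in opposite directions. They had 56 rises and 26 falls in common, where independent lists would share 84.1 and 64.8. Fold change ran with expression level in S2A-S7A (rank correlation 0.48) and against it in WT18 (-0.44), and how much of r comes from this was not tested.

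**Figure D3:**
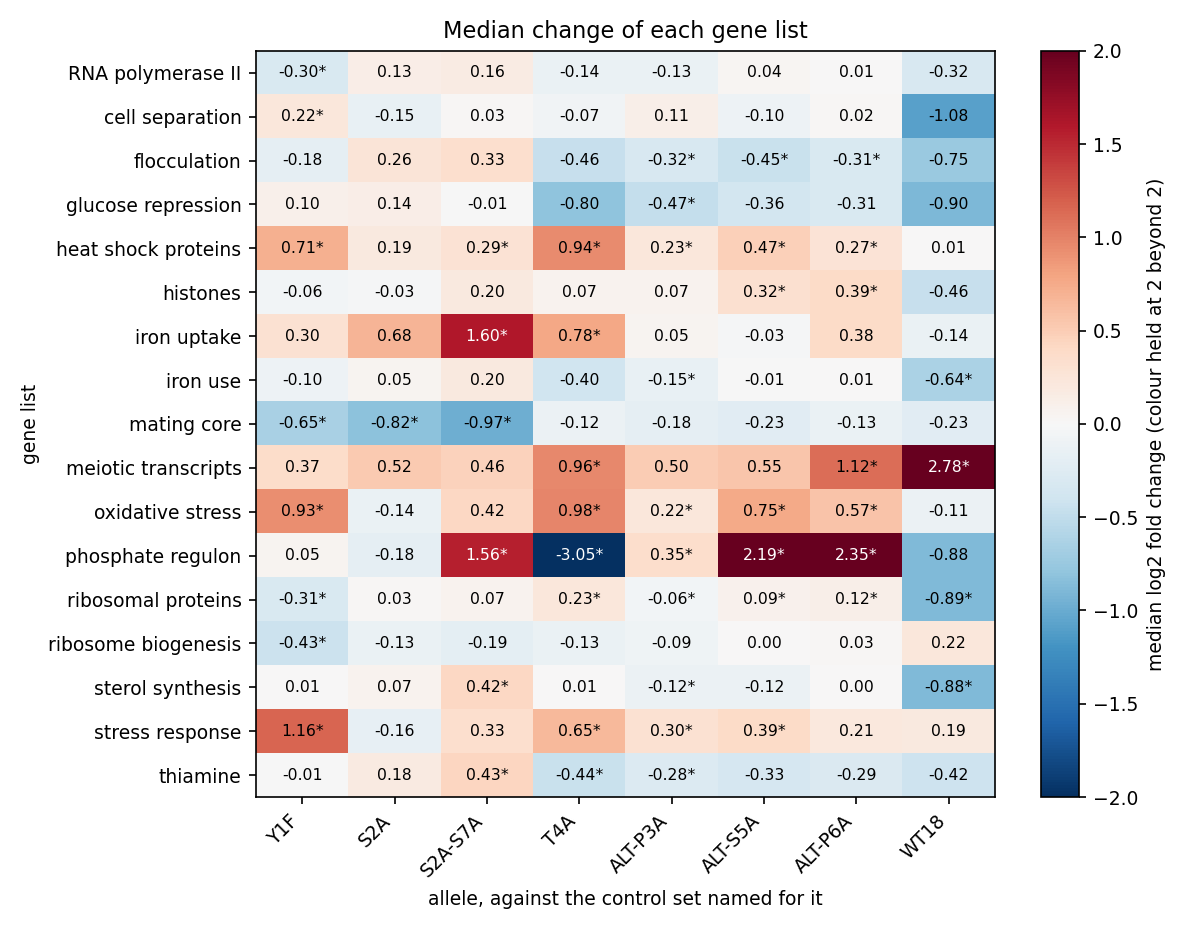
Median log2 fold change of each of the 17 gene lists that passed camera with the preset correlation in any allele, drawn for each of the 8 alleles, with an asterisk where it passed. No list passed with an estimated correlation. The phosphate genes run from -3.05 in T4A to 2.35 in ALT-P6A.

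In a comparison chosen after the results were seen, genes at the chromosome ends fell more often than others in the CTD mutants. Among the 90 genes at 3 chromosome ends (30 outermost genes each, without the right end of chromosome I), 38.9% fell at least 2-fold in Y1F, against 4.39% of the genes elsewhere, and 46.7% against 7.2% did in T4A. The shares were 34.4% against 2.28% in ALT-S5A, 35.6% against 2.72% in ALT-P6A, 18.9% against 0.79% in ALT-P3A, 25.6% against 5.2% in S2A and 22.2% against 9.38% in S2A-S7A. Against the other control set the odds ratios of these 7 alleles ran from 3.11 (S2A-S7A) to 14.2 (ALT-S5A and ALT-P6A). In WT18 the shares were 17.8% and 11.6% (p = 0.095, Fisher's exact test), with an odds ratio of 2.39 against control set 1 (p = 0.0027). Rises were also more frequent at the ends in S2A (24.4% against 6.94%) and S2A-S7A (24.4% against 5.6%), with odds ratios of 3.13 and 5.17 against control set 2. The rises in ALT-P6A (10% against 3%), ALT-S5A (6.67% against 2.87%) and T4A (10% against 5.11%, p = 0.051) had odds ratios of 1.64, 1.09 and 1.91 against control set 1, where none passed Fisher's exact test (p = 0.21, 0.82 and 0.11). Genes at the ends also differed more often between the control sets, which have no allele change by their label: 15.6% against 4.85% were higher and 10% against 3.62% lower in set 2. Neighbouring genes are not independent replicates, which Fisher's exact test takes them to be. Reads shared with copies elsewhere were looked at only near the right end of chromosome I, not at these 3 ends.

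**Figure D4:**
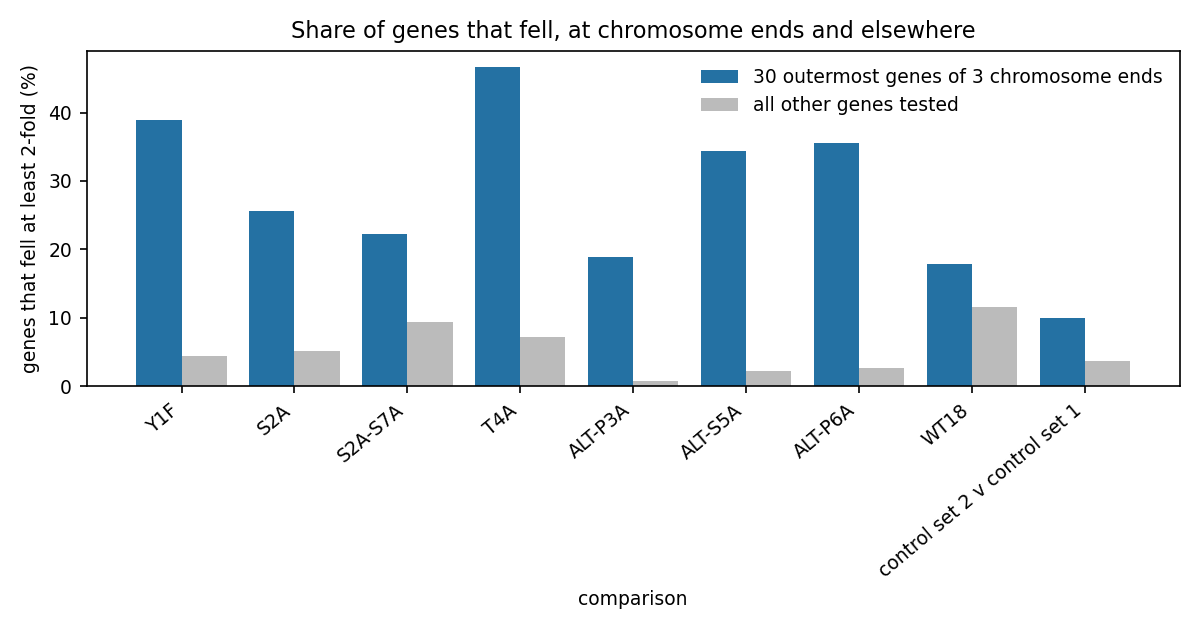
Percent of genes called at least 2-fold lower at 3 chromosome ends (30 outermost genes each) and elsewhere in each comparison. The share at the ends was higher in 7 alleles, and in WT18 the difference did not pass (p = 0.095, Fisher's exact test).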

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

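The tests chosen only after the results were seen are those of the gene effects in the next paragraph, of the rebuilt control means, of the shifts shared between control set 2 and other groups, of loss and shared reads at the right end of chromosome I, of the other chromosome ends and of the WT18 pairs.

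The phosphate effects of T4A and ALT-P6A differed by a test of the difference itself: -5.94 (log2) for pho1, -4.41 for pho84 and -4.53 for tgp1, T4A minus ALT-P6A. The str3 effect of S2A minus that of S2A-S7A was -4.09. Between the 2 new and the 2 earlier WT18 libraries, hsp16 differed by 5.62 and mug108 by 5.03 (log2, new minus earlier). With all libraries scaled together, the spo5 level in WT18 replicate 4 was 5.19 CPM, against 6.86 to 6.97 in the other 3. This gap lies past the bound that chance passes in about 1 in 20 groups of 4. Of 25 measures tested this way 1 passed, which is about the number chance gives.

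Control set 2 differs from control set 1 in 537 genes although the strain label is 1. A difference in depth is argued against, since 543 genes were called with every library thinned to the smallest total. A shift of all set-2 libraries is argued against, since the lowest share of the shift in a set-2 mutant minus the highest in a set-1 mutant was -0.15. Open are that the count columns are not the libraries behind the authors' control means, which weighted sums missed by 25%, and that control set 2 and the ALT alleles share a difference, the lowest ALT share being 0.79 against 0.16 at most for a left-out control library. That control set 1 stands apart from every other group also stays open, since the lowest share of the 7 mutants was 0.38, between the bounds set for and against it. No biological explanation was tested.

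Of the genes near the right end of chromosome I, 5 neighbours fell in Y1F and in T4A. Among the 30 outermost genes tested at that end, 14 fell and 3 rose at least 2-fold in Y1F, and 6 fell and 4 rose in T4A. The lowering was not confined to these alleles. The log2 fold change of gdt1 was -2.3 in S2A, -4.76 in ALT-S5A, -3.59 in ALT-P6A, -1.82 in WT18, -0.81 in ALT-P3A and 0.88 in S2A-S7A. That of ftm4 ran from -7.46 (T4A) to -1.98 (ALT-P3A) over the 8 alleles. Within S2A the gdt1 level ran from 2.68 to 33.8 CPM. Within WT18 it was 2.74 and 6.63 CPM in the new pair but 96.7 and 104 CPM in the earlier pair, against 170 to 191 CPM in control set 2. The WT18 value is thus an average over unlike pairs. Reads shared with copies elsewhere are argued against for SPAC186.04c, gdt1 and SPAC186.06, of whose 50-base windows 0% recur, and stay open for SPAC750.01 and ftm4, with 32.8% and 92.4%. Loss of the region stays open: the median was 2.5 counts per library, but gdt1 kept 9 in Y1F and 15 in T4A, and SPAC750.01 24 and 32. Lower expression at chromosome ends in general, with an odds ratio of at least 11.3 at the other 3 ends in either allele, also stays open. The counts do not tell whether DNA is present.

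WT18 differs from control set 2 in 2242 genes. The mix of its libraries is argued against as the whole cause, since either pair alone called at least 1588 genes against either control set, more than any other allele. A separate difference of each pair, in protocol or strain, stays open. With no control library in common the pairs shared 748 or 997 genes in direction, where independent lists would share 339 or 388. They had 111 or 107 in opposite directions, against 272 or 336. Independent lists take no account of expression level, against which the fold change ran, so the excess alone does not decide this. For genes that only 1 pair called, a separate difference was not tested. A test set before, on genes called with all 4 libraries, let the pairs share controls and is not used. With a trend with expression level taken off the fold changes, 1780 genes passed the 2-fold cut (993 higher and 787 lower), 1340 of the 2242 among them. Their adjusted p-values were those of the fit before its removal. This therefore does not decide whether the trend is the whole cause. The shorter CTD stays open as the biological explanation, beside any difference of control set 2 and of each pair.

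Regrouping the libraries tested whether other groupings call as many genes. For WT18, 1 of 35 splits, the real one, called 2242 genes and the highest other 0 by edgeR, so that chance is argued against there (4430 genes at an unadjusted p under 0.05, and 2482 in the highest other). For the other 13 comparisons the 10 splits are too few for a share under 0.05: in each 1 split, the real one, had the real count and the highest other had 0, with at most 949 genes at an unadjusted p under 0.05 (a T4A split). Of the real counts, the lowest was 4, for ALT-P6A against ALT-S5A.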

How the results depend on the processing

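The other control set alone was chosen as an alternative after the data were seen; the others were set before. Scaling by DESeq2's factors, the DESeq2 test and no filter beyond 1 count kept every count of called genes within 1.5 times, and each named gene kept its side of the threshold but pho84 in ALT-P3A. Where a cause is not given, the cause was not tested.

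With no minimum fold the counts were, by the construction of that alternative, 3072 for Y1F, 2150 for S2A, 3629 for S2A-S7A, 2456 for T4A, 2608 for ALT-P3A, 2007 for ALT-S5A, 2764 for ALT-P6A, 4280 for WT18, 2080 for S2A-S7A against S2A, 2562 for Y1F against S2A, 1768 for ALT-P3A against ALT-P6A, 1296 for ALT-P3A against ALT-S5A, 19 for ALT-P6A against ALT-S5A and 2659 for the control sets. With the control sets together they were 474 for T4A, 91 for ALT-P3A, 233 for ALT-S5A and 249 for ALT-P6A. With the other control set alone they were 560 for ALT-P3A, 629 for ALT-S5A and 583 for ALT-P6A. With all groups of the control set in 1 fit, 103 genes differed between ALT-P3A and ALT-P6A, 105 between ALT-P3A and ALT-S5A, and 0 by edgeR between ALT-P6A and ALT-S5A (861 at an unadjusted p under 0.05 with only those groups and control set 2 in the fit, where DESeq2 called 5). In that fit, of the named genes 8 of 26 did not pass in ALT-P3A, 3 of 27 in ALT-S5A, 3 of 28 in ALT-P6A, 1 of 8 in each contrast with ALT-P3A and 2 of 2 between ALT-P6A and ALT-S5A, all in the same direction, and 0 in the other comparisons. For control set 2 the fit included WT18, whose new libraries had 658 genes called higher and 142 lower than its earlier ones. Whether this spread cost the calls was not tested. With the 2 earlier WT18 libraries alone, 2 of 25 named WT18 genes did not pass, and with the 2 new ones alone 0.

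With replicate number as a block the counts were 588 for Y1F, 797 for S2A, 957 for S2A-S7A, 278 for S2A-S7A against S2A, 605 for Y1F against S2A, 191 and 152 for ALT-P3A against ALT-P6A and ALT-S5A, and 7 for ALT-P6A against ALT-S5A. Without 1 library the counts ran from 157 to 475 for ALT-P3A (475 without control set 2 replicate 5), from 167 to 398 for S2A-S7A against S2A (without S2A replicate 3 and 1) and from 1 to 8 for ALT-P6A against ALT-S5A. The totals of the other 11 comparisons kept within 1.5 times, but not each direction. Without control set 2 replicate 5 the rises went from 317 to 489 in T4A, from 180 to 280 in ALT-S5A and from 190 to 353 in ALT-P6A, and the genes lower in control set 2 than in set 1 from 233 to 412.

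With an estimated correlation 0 gene lists passed camera in any comparison: 0 of 8 for Y1F, 0 of 1 for S2A, 0 of 6 for S2A-S7A, 0 of 8 for T4A, 0 of 10 for ALT-P3A, 0 of 7 for ALT-S5A, 0 of 7 for ALT-P6A and 0 of 4 for WT18. Of the RNA classes 1 passed with it in T4A, ALT-P3A, ALT-P3A against ALT-P6A and ALT-P6A against ALT-S5A, and 0 in the other comparisons.

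Some named genes turned direction (log2 fold change). With the other control set alone these were, in Y1F, SPBPB21E7.04c (2.94), SPCC737.04 (3.27), cbp6-antisense-1 (1.03), mei2 (0.78) and spk1 (0.11); in S2A, SPBPB2B2.06c (-0.19), SPCC737.04 (2.19), SPBPB21E7.04c (3.14), isp5 (0.10) and pho84 (0.08); in S2A-S7A, SPCC737.04 (3.12), SPBPB21E7.04c (3.58), omt3 (0.13), cbp6-antisense-1 (1.78) and ste11 (0.28); in T4A, SPBPB21E7.04c (-3.28) and SPCC737.04 (-3.03). In ALT-P3A they were rec10 (-0.76), SPCC1235.18 (0.43), SPBPB10D8.01 (0.18), SPBPB2B2.06c (1.85), SPAC2H10.01 (0.73), SPBPB10D8.02c-antisense-1 (0.09) and pho84 (-0.53); in ALT-S5A, mug147 (-0.26), SPBPB2B2.06c (0.59), SPAC2H10.01 (0.34) and omt3 (-1.15); in ALT-P6A, SPAC2H10.01 (0.50) and omt3 (-1.42); in WT18, rpl2001-antisense-1 (0.15) and rpb1 (0.46). With the control sets together, SPBPB21E7.04c (-2.23) and SPCC737.04 (-1.98) turned in T4A, rec10 (-0.03) and pho84 (-0.22) in ALT-P3A, and omt3 in ALT-S5A (-0.25) and ALT-P6A (-0.55).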

Other observations

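The tests chosen only after the results were seen are the length correlations against the matched controls and the medians by introns; the correlations against control set 1 were set before.

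Shorter coding genes tended to rise and longer ones to fall in T4A, ALT-S5A and ALT-P6A, with rank correlations of log2 fold change with exon length of -0.33, -0.32 and -0.33 across genes, which are not independent replicates. A candidate explanation is that control set 2 brings the trend. Against control set 1 the correlations were -0.26, -0.20 and -0.24, which leaves a part from that control open. In ALT-P3A, which was not part of that test, the correlation was -0.21, and -0.12 against control set 1. In WT18 the median log2 fold change was -0.25 for 2436 intronless coding genes and 0.29 for 1303 genes with at least 2 introns.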
